A study of Saccharomyces cerevisiae with 55 samples.

How the data were processed

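RNA from budding yeast (Saccharomyces cerevisiae) was measured on 2-colour expression arrays. Each array compared a strain carrying a mutated histone H4 with a parental strain. In the mutants, lysines 5, 8, 12 and 16 of the H4 N-terminal tail were replaced by arginine in all 15 combinations. Arginine keeps the positive charge of lysine but cannot be acetylated, so such substitutions are commonly used to imitate the unacetylated residue. Per the labels, channel 1 of every array held RNA of the parental strain MDY453 (35 arrays) or MDY470 (20 arrays), and channel 2 held RNA of the mutant. The 55 arrays cover 30 mutant strains, 17 with K16R and 13 without. All arrays of the quadruple mutant and of K5R/K12R/K16R were against MDY453 and all of K8R/K12R against MDY470, so the sets differ in the mutants they hold. Of the strains MDY472 to MDY487, MDY484 (K5R/K12R/K16R), MDY486 and MDY487 (quadruple mutant) were against MDY453 and the rest against MDY470. The labels do not say why. Every mutant had 2 strains except K8R/K12R with 1 and the quadruple mutant with 3. A pair of arrays of the quadruple mutant labelled as technical replicates (r = 0.927 across genes, no identical columns) was averaged and counted as 1 sample, which left 54 samples.

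The deposited table holds a log2 ratio per probe and array. The base, the direction, the dyes, the background correction and the normalization that the authors used are not given in the sources used here, nor are spot intensities. Base 2 was inferred from the largest size in the table, 6.64, which is log2 of a ratio of 100. No array pair correlated below 0 (lowest r 0.00541 of 1485 pairs), so no array ran against the others. A positive value likely means more RNA in the mutant than in the parental strain: the parental strain is the reference on every array, and a ratio is usually written as test over reference. Array medians lay between -0.0704 and 0.0537. The gene annotation given with the platform names 1 gene for 5570 of the 6720 probes, several genes for 0 and none for 1150. Of the named probes, 5565 were matched to the R64 reference gene table, used only for current names and for which genes lie near a chromosome end, taken as the outer end of the last annotated gene. Probes of the same gene were averaged per array (29 genes had more than 1 probe), which gave 5540 genes, 5330 of them with a value in every sample.

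The table held 5583 missing values, 194 of them in named probes, and 4346 values exactly at the ratio limit of 100, 43 of them in named probes. Values at the limit were treated as missing, and probes without a gene name were left out. Both decisions were made after the table had been seen, and both alternatives were run. Each array was centred on its median. Genes needed a value in at least 2 of 3 samples and in at least 1 sample of every mutant, which removed no gene. The number of arrays limits the precision, and without intensities weak spots could not be told from strong ones.

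Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg threshold 0.05 over the 5540 genes). All adjusted p-values for single genes come from limma. The additive model had an intercept and a term for each of K5R, K8R, K12R and K16R, so a site effect is the mean change that a substitution added over the backgrounds tested. Further tests covered the mean of K5R, K8R and K12R, the difference of K16R from that mean, differences among those 3 sites, the change of the K16R effect with the number of other substitutions, and the 6 pairwise products. A second model gave each mutant its own mean, tested against 0. That test leaves out the spread of the parental strain itself. The mutant strain was a random block (estimated correlation 0.346 in the site model and 0.205 in the mutant model). Some labels name biological replicates, but they do not say that every array came from a separate culture. The p-values therefore measure the spread between these samples and strains, part of which may be technical.

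The comparisons, the tests, the other ways of fitting, the rule for named genes and 40 gene lists were fixed before the data were examined. Named genes were the 12 highest and 12 lowest K16R effects past the threshold with the same sign in at least 6 of the 7 matched pairs of mutants that differ by K16R alone. For the mean of K5R, K8R and K12R they were the 10 highest and 10 lowest. Each of K5R, K8R and K12R gave 3 genes per direction, and each test of differences or interactions gave the 6 smallest p-values. The quadruple mutant and the K16R mutant gave 5 genes per direction, and the other mutants 1. Each list gave up to 4 members per effect by the size of the moderated statistic, past the threshold or not, and every measured silent cassette and histone gene was named. Genes named outside this rule are said to be so.

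Lists of at least 5 measured genes were tested with camera (preset correlation 0.01) for K16R and for the mean of K5R, K8R and K12R, and p-values were adjusted over the 76 tests of 38 lists. The lists of mitochondrially encoded genes and of retrotransposon genes had 0 measured members. Since camera takes no block, it ran on the 5330 complete genes after the data had been whitened with the strain correlation. An estimated correlation per list and fry were alternatives. Subtelomeric genes were those within 20 kb of a chromosome end. Probes of duplicated families (PAU, COS, HXT, THI, PHO11 and PHO12, the mating cassettes) can hybridise with other members, so their values are uncertain.

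Spread per array was the SD of the log2 ratios over genes. Its relation to the number of substitutions was tested with 100000 permutations over strains, two-sided. Correlations of site effects across genes are given with the values from 50 simulated data sets without effects, since all effects share the parental channel and the model. In simulated data with the real design and 200 of 5540 genes changed, 97% of genes changed by 0.25 were recovered for the K16R effect, 100% for the mean of K5R, K8R and K12R, 83.6% for the change of the K16R effect with number, and 67.2% for the pairwise products. For the K16R mutant against the parental strain 40.3% were recovered at that size and 95.5% at 0.5. False calls made up 6.6% of the K16R calls and 7.1% of the K16R mutant calls in those data. Alternatives changed the centring, the scaling, the filter, the strain block, the treatment of the 13 arrays with an unexplained "(s)" in the label, the array weights, the parental set, the intercept and the single samples. Further alternatives were added after seeing the data: limit values kept, all probes, and fits without the quadruple mutant, without the 3 arrays with the most limit values, or without 1 K16R array whose label pairs a strain of the MDY453 set with MDY470. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.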

Results

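Gene expression was measured in 15 histone H4 mutants that cover every combination of lysine-to-arginine substitutions at positions 5, 8, 12 and 16 of the H4 N-terminal tail. There were 4 single mutants, 6 double mutants, 4 triple mutants and the quadruple mutant. Each was hybridised against a parental strain with intact lysines on 3 to 5 arrays, 55 in all. After technical replicates were averaged there were 54 samples of 30 strains, 30 samples with K16R and 24 without. Log2 ratios are given as likely mutant over parental, because the parental strain was the reference in channel 1 of every array. Neither the dyes nor the direction is given in the sources used here. Arrays of the same mutant correlated with a median r of 0.809 across genes (77 pairs), and arrays of different mutants with a median of 0.509 (1408 pairs). Genes are not independent replicates, so these values only describe the arrays.

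The expression change grew with the number of substituted lysines. The SD of the log2 ratios over genes averaged 0.185 ± 0.0488 (SD over strains) in 8 strains with 1 substitution, 0.275 ± 0.0478 in 11 strains with 2, 0.421 ± 0.0424 in 8 strains with 3, and 0.651 ± 0.0368 in the 3 strains of the quadruple mutant. HSP12, a small heat shock protein of the plasma membrane induced by stress, followed this order. Its mean log2 ratio was 0.07 ± 0.11 (SD, n = 3) in the K5R mutant, 0.67 ± 0.12 (n = 4) in K5R/K8R, 3.11 ± 0.28 (n = 5) in K5R/K8R/K12R and 4.35 ± 0.50 (n = 4) in the quadruple mutant. PHO12, a secreted acid phosphatase, went the other way, with 0.10 ± 0.06, -0.34 ± 0.33, -1.96 ± 0.39 and -4.12 ± 0.78 in the same mutants. Over the 30 strains the SD correlated with the number of substitutions (r = 0.93, rho = 0.907, permutation p = 1e-05 for each, the smallest these permutations can give). Without the 2 strains farthest from the median number r was 0.913. Within the arrays against MDY453 r was 0.954 over 17 strains (p = 1e-05, permutation), and within those against MDY470, which hold no quadruple mutant, it was 0.812 over 14 strains (p = 6e-04, permutation).

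**Figure D1:**
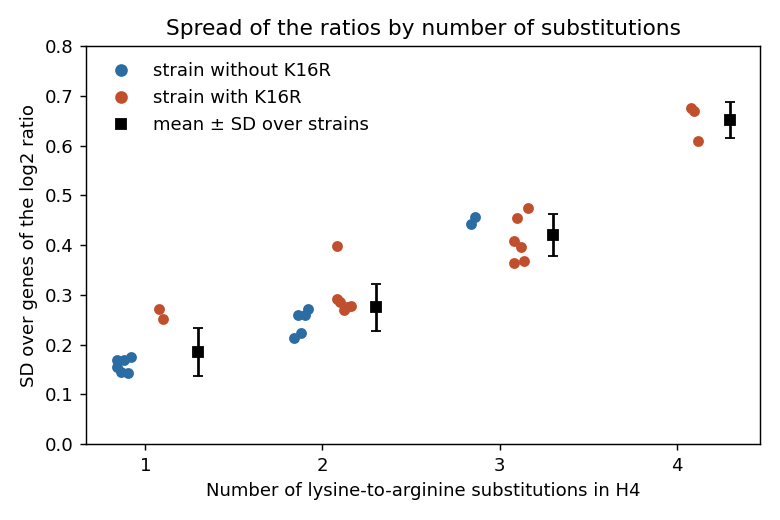
SD of the log2 ratios over genes for each mutant strain (vertical axis) against the number of substituted lysines (horizontal axis), with points for strains and bars for the mean and SD over strains. The means rise from 0.185 with 1 substitution to 0.651 with 4.

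Strains with K16R had little RNA of the genes that mark a haploid yeast cell of mating type a. All 7 measured a-specific genes fell. Among them were MFA2 and MFA1, which encode the a-factor pheromone, with K16R effects of -3.14 ± 0.18 and -2.87 ± 0.13 (SE, 54 samples), or 8.80-fold and 7.30-fold lower. STE2, the receptor for alpha-factor, fell by 2.69 ± 0.13, the alpha-factor protease BAR1 fell by 2.54 ± 0.11, the agglutinin subunit AGA2 fell by 2.13 ± 0.09, and the a-factor exporter STE6 fell by 2.03 ± 0.11. The same held for genes that haploid cells of either mating type use to respond to pheromone. GPA1, the G protein alpha subunit, was 8.08-fold lower (-3.01 ± 0.10, adjusted p = 9.36e-32), FAR1, which arrests the cell cycle in response to pheromone, was 4.60-fold lower (-2.20 ± 0.07, adjusted p = 4.2e-34), and the MAP kinase FUS3 was 4.49-fold lower (-2.17 ± 0.12). RME1, a repressor of meiosis, fell by 1.56 ± 0.05, and NEJ1, a haploid factor of DNA end joining, fell by 1.48 ± 0.08.

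The separation was complete for the genes plotted sample by sample. STE2 lay between -4.07 and -0.99 in the 30 samples with K16R and between -0.24 and 0.34 in the 24 without it. GPA1 ranged from -4.09 to -1.80 with K16R and from -0.24 to 0.21 without it, MFA1 from -3.72 to -1.17 against -0.09 to 0.74, and FAR1 from -2.48 to -1.18 against -0.36 to 0.41. MFA2, GPA1, MFA1, STE2, BAR1, FAR1, FUS3, AGA2, STE6 and RME1 were lower in 7 of the 7 pairs of mutants that differ by K16R alone. As a list, the a-specific genes fell (7 of 7 over all genes and 7 adjusted over the list alone; camera adjusted p = 9.61e-19, and adjusted p = 0.000197 with an estimated correlation). Of 29 haploid-specific and pheromone response genes 20 fell, 1 rose and 8 did not pass, with 23 lower and 1 higher adjusted over the list alone (camera adjusted p = 5.3e-24, and adjusted p = 3.5e-05 with an estimated correlation).

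**Figure D2:**
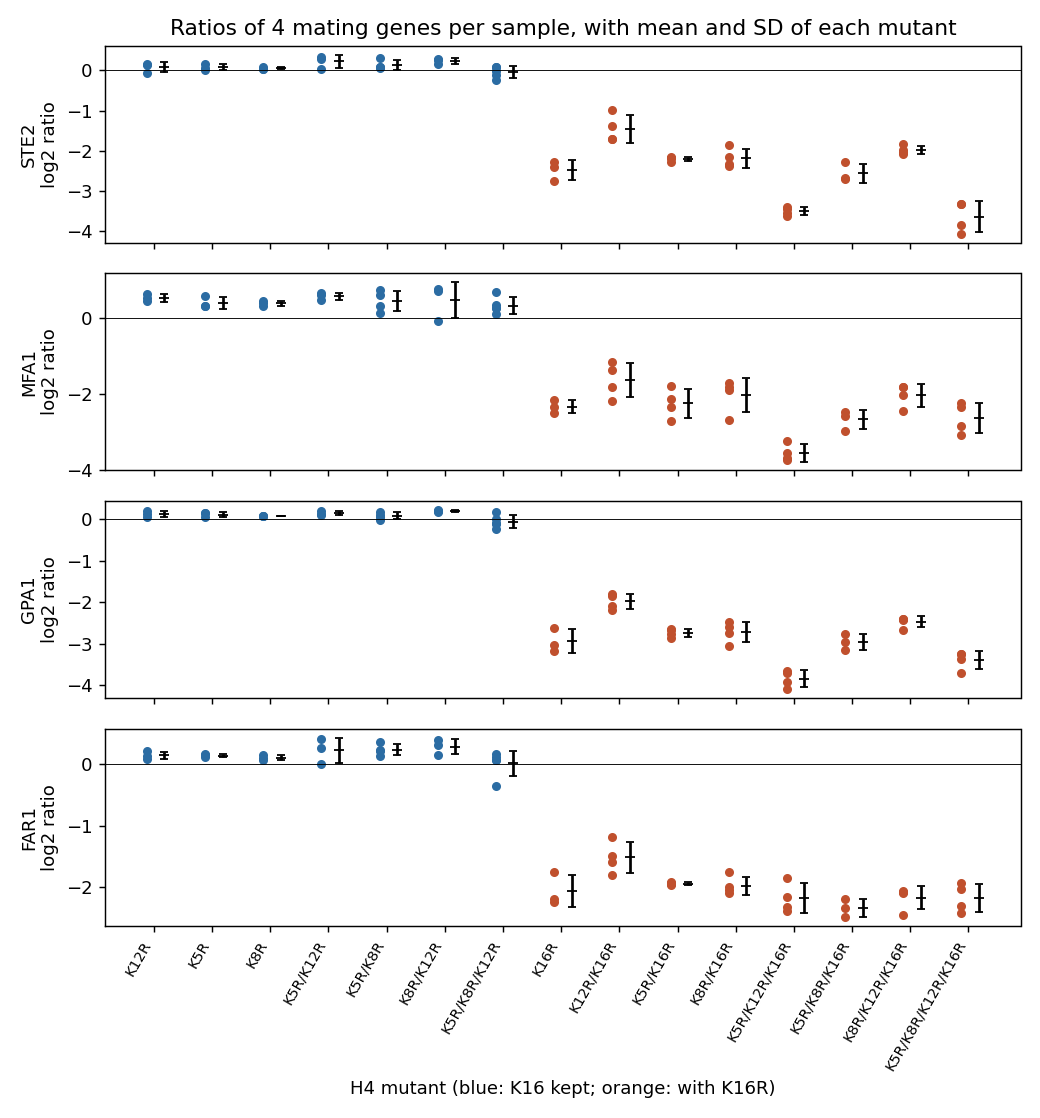
Log2 ratio (vertical axes) of STE2, MFA1, GPA1 and FAR1 in every sample of the 15 mutants (horizontal axis), with a point per sample, blue without K16R and orange with it. No sample with K16R reaches the range of the samples without it, and GPA1 stays below -1.80 with K16R and above -0.24 without it.

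Genes of the opposite mating type moved far less. Of 5 alpha-specific genes 3 rose slightly with K16R: the pheromone genes MF(ALPHA)1 (0.22 ± 0.08) and MF(ALPHA)2 (0.13 ± 0.04) and the agglutinin gene SAG1 (0.19 ± 0.06). AFB1, which encodes a-factor barrier, fell by 0.79 ± 0.10. The counts adjusted over the list alone were 3 higher and 1 lower, and the list as a whole was not called (camera adjusted p = 0.939). SAG1 turned to -0.03 when the model had no intercept. None of the 6 probes for the silent mating cassettes and MAT genes passed with K16R in limma (0 at the threshold, 0 adjusted over the list alone, list adjusted p = 0.671). HMLALPHA1, the cassette copy of the alpha1 activator, had an effect of 0.16 ± 0.08 (adjusted p = 0.102), HMLALPHA2 0.09 ± 0.10, HMRA1 -0.14 ± 0.11, HMRA2 0.08 ± 0.10, MATALPHA1 0.14 ± 0.15 and MATALPHA2 0.07 ± 0.10. With the mean of K5R, K8R and K12R these 6 genes also had 0 past the threshold and 0 adjusted over the list alone, between 0.04 (HMRA1) and 0.13 (MATALPHA1).

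Many genes near chromosome ends were lower with K16R, among them genes that do not belong to a common pathway. Of 233 genes within 20 kb of an end 79 fell, 44 rose and 110 did not pass (80 lower and 45 higher adjusted over the list alone). SRY1, a dehydratase of 3-hydroxyaspartate, fell by 2.13 ± 0.11, AIF1, a homologue of the mammalian apoptosis-inducing factor, fell by 1.45 ± 0.10, SNO2, of the vitamin B6 genes, fell by 1.37 ± 0.10 and FDC1, a decarboxylase of aromatic acids, fell by 0.97 ± 0.05. Under 5 kb 27.6% of 58 genes were lower and 19% higher, with the lowest median effect (-0.0911). Between 5 and 10 kb 34.5% of 58 genes were lower, between 10 and 20 kb 36.8% of 117, between 20 and 40 kb 30.2% of 262, and beyond 40 kb 17.7% of 5040. The camera call was lost when the correlation was estimated (adjusted p = 0.000496, and adjusted p = 0.559 with an estimated correlation). The list was not called for the mean of K5R, K8R and K12R, where 87 genes were higher and 48 lower, the same 87 and 48 adjusted over the list alone (adjusted p = 0.171).

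**Figure D3:**
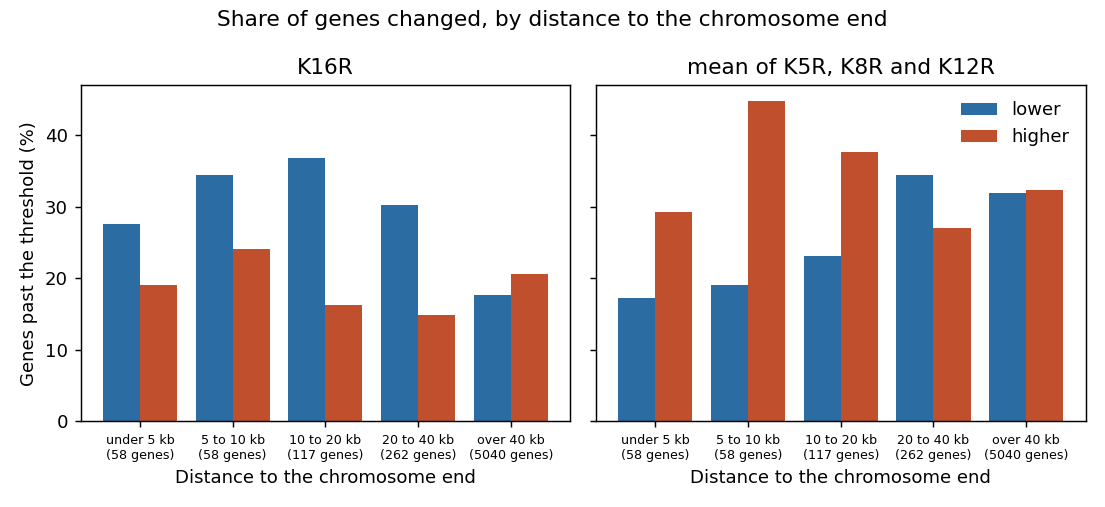
Percent of genes higher and lower (vertical axis) with K16R and with the mean of K5R, K8R and K12R by distance from the nearest chromosome end in kb (horizontal axis). With K16R the share of lower genes is 36.8% between 10 and 20 kb and 17.7% beyond 40 kb.

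Subtelomeric gene families did not move as a block. Of 23 seripauperin genes, which encode small cell wall proteins, 18 rose with K16R (22 adjusted over the list alone), led by PAU23 (0.49 ± 0.07) and PAU17 (0.42 ± 0.08). The call was lost with an estimated correlation (adjusted p = 1.64e-05, and adjusted p = 0.559 with an estimated correlation), and PAU24 turned to -0.08 without an intercept. Of 12 COS genes, which encode membrane proteins of endosomal sorting, 8 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.458). COS10 fell by 1.44 ± 0.21 and COS9 fell by 0.79 ± 0.08, while COS5 (0.29 ± 0.06) and COS3 (0.26 ± 0.05) rose. Of 23 thiamine genes 7 fell and 5 rose, also adjusted over the list alone (adjusted p = 0.123). SNZ2 (-1.44 ± 0.11), SNO2 and SNO3 (-1.23 ± 0.09), all of vitamin B6 metabolism, were among those that fell. The median of that list was 0.0927 and its mean -0.207, so these differ in sign. Probes of these families can cross-hybridise.

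The genes that rose most with K16R were HPF1, a cell wall mannoprotein (1.53 ± 0.10, 2.88-fold, adjusted p = 2.02e-18), and YAR068W, which encodes a protein of unknown function (1.08 ± 0.09). HSP12 (1.06 ± 0.13), INO1, which makes inositol phosphate (0.93 ± 0.09), CSS1 (0.93 ± 0.08), the proline oxidase gene PUT1 (0.91 ± 0.16), NCA3 (0.74 ± 0.08), BTN2 (0.74 ± 0.08), RTS3 (0.74 ± 0.10), ARG1 of arginine synthesis (0.71 ± 0.09), ATG41 of autophagy (0.70 ± 0.05) and HSP30 (0.70 ± 0.17) followed. CSS3 fell by 1.96 ± 0.18. In all, 1122 genes rose and 1053 fell with K16R, 2175 of 5540 (39.3%), 3 of them higher and 34 lower by at least 2-fold. Within the MDY453 arrays the count was 1338 and within the MDY470 arrays 685. Without an intercept it was 1259.

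Stress genes, chaperones and oxidative phosphorylation genes rose with K16R. Of 55 general stress response genes 43 rose and 2 fell (45 and 2 adjusted over the list alone), including the mitochondrial chaperone HSP78 (0.68 ± 0.06), the trehalose phosphatase TPS2 (0.54 ± 0.07) and the transketolase TKL2 (0.45 ± 0.05). Camera gave adjusted p = 1.76e-14, and adjusted p = 0.18 with an estimated correlation. Of 28 chaperones of the heat shock response 20 rose (21 adjusted over the list alone), such as SSA3 (0.62 ± 0.07) and STI1 (0.38 ± 0.05), with adjusted p = 4.02e-10, and adjusted p = 0.0943 with an estimated correlation. Of 39 nuclear genes of oxidative phosphorylation 28 rose (29 adjusted over the list alone), such as ATP1 (0.53 ± 0.09), INH1 (0.49 ± 0.08), SDH1 (0.48 ± 0.08) and COR1 (0.41 ± 0.06), with adjusted p = 1.14e-09, and adjusted p = 0.303 with an estimated correlation. This call was not met within the MDY470 arrays (adjusted p = 0.0679).

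Lists of amino acid, sulfur, ribosomal protein and G2/M genes were also called for K16R. Of 59 amino acid biosynthesis genes 29 rose and 3 fell (29 and 4 adjusted over the list alone), among them ARG3 (0.58 ± 0.06), ILV2 (0.41 ± 0.04) and HOM3 (0.38 ± 0.05), with adjusted p = 1.43e-06, and adjusted p = 0.303 with an estimated correlation. Of 27 genes of sulfur and methionine metabolism 15 rose and 4 fell, also adjusted over the list alone, with MET3 (0.40 ± 0.08), MET10 (0.39 ± 0.07), MET28 (0.34 ± 0.05) and MUP3 (0.33 ± 0.05) as examples. That list had adjusted p = 0.0213, adjusted p = 0.446 with an estimated correlation, and adjusted p = 0.0994 within the MDY470 arrays. Of 133 cytosolic ribosomal protein genes 21 fell and 3 rose (14 and 2 adjusted over the list alone), such as RPL22B (-0.30 ± 0.07), RPL43B (-0.27 ± 0.05), RPL42A (-0.25 ± 0.06) and RPS3 (-0.20 ± 0.05). This call was weak (adjusted p = 0.0403, and adjusted p = 0.76 with an estimated correlation) and its direction turned to higher within the MDY470 arrays (adjusted p = 0.0431). Of 23 G2/M cell cycle genes 11 fell and 1 rose, also adjusted over the list alone. WSC4 (-0.53 ± 0.07), FRK1 (-0.41 ± 0.04) and CDC20, an activator of the anaphase-promoting complex (-0.29 ± 0.03), fell and the chitin synthase gene CHS2 rose (0.29 ± 0.04), with adjusted p = 0.00536, and adjusted p = 0.234 with an estimated correlation.

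Several further lists held genes with clear K16R effects without being called as a whole. Of 28 genes expressed at the M/G1 boundary 5 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.138). RME1, AMN1 (-0.84 ± 0.06), the transcription factor gene TEC1 (-1.09 ± 0.08) and the chitin synthase gene CHS1 (-0.39 ± 0.06) had the smallest adjusted p. PST1, also a cell wall gene, rose by 0.25 ± 0.08 but was at -0.06 within the MDY470 arrays. Of 60 meiosis and sporulation genes 20 rose and 17 fell (21 and 17 adjusted over the list alone, adjusted p = 0.626), with the RNA methyltransferase gene IME4 at -0.91 ± 0.05, SSP1 at -0.55 ± 0.07, ZIP2 at -0.31 ± 0.05 and OSW1 at 0.35 ± 0.05. Of 36 cell wall genes 15 rose and 6 fell (16 and 6 adjusted over the list alone, adjusted p = 0.217), UTR2 at -0.57 ± 0.05, CRH1 at 0.46 ± 0.07 and CWP2 at 0.36 ± 0.06. Of 21 phosphate genes 5 fell and 1 rose (4 and 1 adjusted over the list alone, adjusted p = 0.186), PHO11 at -0.95 ± 0.15, PHO3 at -0.52 ± 0.06 and PHO81 at -0.39 ± 0.08. Of 19 purine genes 8 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.138), among them ADE1 (-0.43 ± 0.08), ADE17 (-0.37 ± 0.08), HPT1 (-0.26 ± 0.06) and ADE13 (-0.20 ± 0.05).

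The other lists were mixed for K16R. In the tricarboxylic acid and glyoxylate cycle 9 of 26 genes rose and 4 fell (10 and 5 adjusted over the list alone, adjusted p = 0.148), with FBP1 of gluconeogenesis at 0.52 ± 0.06, IDP2 at 0.35 ± 0.05, PYC1 at 0.30 ± 0.05 and PYC2 at 0.26 ± 0.05. Of 34 proteasome genes 7 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.217), RPN4 at 0.39 ± 0.06 and RPN3 at 0.19 ± 0.03. Of 65 mitochondrial ribosomal protein genes 6 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.785), MRP20 at 0.21 ± 0.05 and MRPS18 at -0.27 ± 0.07. Of 20 subunits of RNA polymerases I and III 4 rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.785), RPC34 at -0.39 ± 0.07, RPC31 at -0.36 ± 0.09 and RPA190 at 0.17 ± 0.05. Of 117 ribosome biogenesis genes 13 fell and 11 rose, with SQT1 (adjusted p = 0.000903) among the lower ones and NOP56 (0.22 ± 0.06) and RRP12 (0.19 ± 0.04) among the higher ones.

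Among the lists tested, substitution of lysines 5, 8 and 12 raised stress and respiration genes and lowered phosphate and ribosome synthesis genes. With an estimated correlation only the stress list kept its call. Averaged over these 3 sites, HSP12 rose by 1.39 ± 0.08 per substitution (SE, 54 samples; 2.62-fold, adjusted p = 9.43e-22), PUT1 by 1.22 ± 0.09, the stress gene DDR2 by 1.21 ± 0.07 and RIM4, a regulator of meiosis, by 1.14 ± 0.08. MSC1 (0.92 ± 0.05), INO1 (0.90 ± 0.05), RTC3 (0.87 ± 0.06), the hexokinase gene HXK1 (0.81 ± 0.05), TMA10 (0.79 ± 0.09) and the glycogen phosphorylase gene GPH1 (0.78 ± 0.05) rose as well. PHO12 (-1.17 ± 0.09) and PHO11 (-1.14 ± 0.09), near-identical acid phosphatase genes, fell most, 2.26-fold and 2.20-fold. AIF1 (-1.01 ± 0.06), the phosphate pathway kinase inhibitor PHO81 (-0.78 ± 0.05), YJL218W (-0.75 ± 0.04), COS12 (-0.70 ± 0.08), the fluoride exporter gene FEX2 (-0.66 ± 0.05), YKL222C (-0.65 ± 0.07), BNA5 of NAD synthesis (-0.64 ± 0.05) and COS10 (-0.63 ± 0.13) followed. COS10 turned to 0.03 when arrays were scaled to 1 spread. Of 5540 genes 1791 rose and 1747 fell (63.9%), 4 higher and 3 lower by at least 2-fold. Within the MDY470 arrays 1699 genes passed.

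Of 55 general stress response genes 54 rose and 1 fell, also adjusted over the list alone, among them HSP42 (0.78 ± 0.05). This was the single list whose call held for these 3 sites with an estimated correlation (adjusted p = 1.12e-27, and adjusted p = 0.0316 with an estimated correlation). Chaperones rose in 22 of 28 genes and fell in 1, also adjusted over the list alone, with BTN2 (0.62 ± 0.05), HSP78 (0.57 ± 0.04) and AHA1 (0.35 ± 0.03) as examples (adjusted p = 4.02e-07, and adjusted p = 0.18 with an estimated correlation). All 23 seripauperin genes rose, also adjusted over the list alone, for example PAU19 (0.60 ± 0.05) and PAU15 (0.60 ± 0.05), with adjusted p = 1.34e-13, and adjusted p = 0.264 with an estimated correlation. Cell wall genes rose in 24 of 36 and fell in 3, also adjusted over the list alone, led by the glucan synthase gene GSC2 (0.73 ± 0.04), CWP1 (0.70 ± 0.05), CWP2 (0.42 ± 0.04) and CCW12 (0.40 ± 0.03). That list had adjusted p = 3.74e-06, and adjusted p = 0.234 with an estimated correlation.

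Respiratory genes rose with the same 3 sites. In oxidative phosphorylation 38 of 39 genes rose, also adjusted over the list alone, such as COR1 (0.48 ± 0.04), CYT1 (0.45 ± 0.04), ATP2 (0.44 ± 0.04) and COX5B (0.39 ± 0.03), with adjusted p = 2.0e-12, and adjusted p = 0.263 with an estimated correlation. In the tricarboxylic acid and glyoxylate cycle 15 of 26 rose and 4 fell (17 and 4 adjusted over the list alone), such as LSC2 (0.37 ± 0.04), IDP2 (0.37 ± 0.03), MDH1 (0.36 ± 0.04) and LSC1 (0.27 ± 0.03), with adjusted p = 0.0163, and adjusted p = 0.446 with an estimated correlation. Mitochondrial ribosomal protein genes, picked by symbol, rose in 38 of 65, also adjusted over the list alone, such as MRP20 (0.24 ± 0.03) and MRPL9 (0.18 ± 0.02). That list had camera adjusted p = 0.000889, and adjusted p = 0.564 with an estimated correlation. Proteasome genes rose in 17 of 34 and fell in 3 (16 and 3 adjusted over the list alone), among them the transcription factor gene RPN4 (0.34 ± 0.03) and PRE7 (0.21 ± 0.02), with adjusted p = 0.0426, and adjusted p = 0.263 with an estimated correlation. The call for the tricarboxylic acid cycle (adjusted p = 0.162) and the one for the proteasome (adjusted p = 0.0905) were not met within the MDY470 arrays, and the proteasome call also ended without centring (adjusted p = 0.0667).

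Genes for making ribosomes fell with the mean of K5R, K8R and K12R. In ribosome biogenesis 101 of 117 genes fell and 0 rose, also adjusted over the list alone, including FAF1 (-0.38 ± 0.04), RRP8 (-0.29 ± 0.03), the helicase gene ROK1 (-0.26 ± 0.03) and RRB1 (-0.26 ± 0.03). Camera gave adjusted p = 1.04e-13, and adjusted p = 0.148 with an estimated correlation. Of 20 subunits of RNA polymerases I and III 16 fell and 1 rose (17 and 1 adjusted over the list alone), among them RPC34 (-0.54 ± 0.04), RPA49 (-0.31 ± 0.04), RPC17 (-0.29 ± 0.04) and RPC25 (-0.24 ± 0.03), with adjusted p = 0.000194, and adjusted p = 0.148 with an estimated correlation. Of 133 cytosolic ribosomal protein genes 86 fell and 1 rose (87 and 1 adjusted over the list alone), such as RPL22B (-0.29 ± 0.04), RPS7B (-0.24 ± 0.04), RPL9B (-0.24 ± 0.03) and RPS3 (-0.22 ± 0.03), with adjusted p = 1.43e-06, and adjusted p = 0.525 with an estimated correlation. Within the MDY470 arrays the last call was not met (adjusted p = 0.481). With K16R the ribosome biogenesis list was not called: 13 genes fell and 11 rose (2 and 7 adjusted over the list alone, adjusted p = 0.638). Within the MDY470 arrays this list was higher with K16R at the preset correlation (adjusted p = 0.000322). Over all arrays an estimated correlation gave adjusted p = 0.948, with the direction lower. The difference between K16R and the mean of the other sites passed for 46 of the 117 genes, each with the K16R effect the higher one (64 adjusted over the list alone).

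Phosphate and purine genes also fell with these 3 sites. Of 21 genes of the phosphate regulon 14 fell and 3 rose, also adjusted over the list alone, among them PHO81, PHO12 and PHO11 (values above), while PHM7 rose by 0.29 ± 0.03 (adjusted p = 0.0042, and adjusted p = 0.337 with an estimated correlation). Of 19 purine biosynthesis genes 13 fell and 3 rose, also adjusted over the list alone, such as ADE17 (-0.49 ± 0.05), ADE1 (-0.42 ± 0.05), ADE13 (-0.23 ± 0.03) and IMD2 (-0.21 ± 0.02), with adjusted p = 0.0042, and adjusted p = 0.272 with an estimated correlation. Of 60 meiosis and sporulation genes 33 rose and 9 fell, also adjusted over the list alone, such as DIT1 (0.53 ± 0.04), the kinase gene IME2 (0.44 ± 0.03), OSW1 (0.39 ± 0.03) and AMA1 (0.33 ± 0.03), with adjusted p = 0.0255, adjusted p = 0.525 with an estimated correlation, and adjusted p = 0.15 within the MDY470 arrays. Of 28 genes expressed at the M/G1 boundary 15 rose and 1 fell, also adjusted over the list alone, such as PIR3 (0.65 ± 0.07), PST1 (0.49 ± 0.05), the chitinase gene CTS1 (0.48 ± 0.06) and PIR1 (0.28 ± 0.03), with adjusted p = 0.0249, and adjusted p = 0.234 with an estimated correlation.

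The amino acid, sulfur and G2/M lists, called for K16R but not for the other 3 sites, were divided under those sites. Their K16R calls were lost with an estimated correlation (values above). The difference between the 2 effects was not tested for whole lists. Of 59 amino acid biosynthesis genes 20 rose and 14 fell, also adjusted over the list alone (adjusted p = 0.775), SER3 at 0.74 ± 0.05, ARG3 at 0.55 ± 0.03, ARG4 at 0.34 ± 0.03 and the transaminase gene BAT2 at -0.50 ± 0.05. Of 27 sulfur and methionine genes 13 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.583), MET28 at 0.41 ± 0.03, STR3 at 0.31 ± 0.04, MHT1 at -0.36 ± 0.03 and SAM1 at -0.24 ± 0.03. Of 23 G2/M genes 10 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 0.208), NCE102 at 0.37 ± 0.03 and CHS2 at 0.25 ± 0.03.

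The mating genes that fell with K16R changed little with the other sites. With the mean of K5R, K8R and K12R, 4 of 7 a-specific genes were lower (5 adjusted over the list alone), MFA2 by -0.42 ± 0.11, STE2 by -0.34 ± 0.08, BAR1 by -0.25 ± 0.06 and STE6 by -0.15 ± 0.07. All 4 turned positive when arrays were scaled to 1 spread, MFA2 to 0.26, STE2 to 0.25, BAR1 to 0.25 and STE6 to 0.32, so no direction is claimed for them. Of 29 haploid-specific and pheromone response genes 6 were higher and 11 lower with the mean of these sites (6 and 10 adjusted over the list alone). DDR48 (0.31 ± 0.04), FIG1 (0.26 ± 0.04) and FIG2 (0.23 ± 0.03) rose, while NEJ1 (-0.31 ± 0.05) turned to 0.14 with scaled arrays. Neither list was called (adjusted p = 0.211 and 0.456). Of the alpha-specific genes 3 rose, also adjusted over the list alone: SAG1 (0.44 ± 0.04), STE3 (0.31 ± 0.05) and MF(ALPHA)1 (0.31 ± 0.05). MF(ALPHA)2 had 0.04 ± 0.02, and that list was not called either (adjusted p = 0.103).

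Each of K5R, K8R and K12R led with the same few genes. These effects are averages over the backgrounds in the additive model and need not hold in the single mutants. In the K5R mutant HSP12 and PHO12 stayed near the parental level (values above). HSP12 rose by 1.19 ± 0.13 with K5R, 1.26 ± 0.13 with K8R and 1.72 ± 0.13 with K12R, and PUT1 by 1.08 ± 0.16, 1.16 ± 0.15 and 1.43 ± 0.15. RIM4 rose by 1.10 ± 0.12 with K5R, and DDR2 by 1.15 ± 0.11 with K8R and 1.47 ± 0.11 with K12R. PHO12 was at -0.95 ± 0.15, -1.22 ± 0.15 and -1.35 ± 0.15, PHO11 at -0.92 ± 0.15, -1.17 ± 0.15 and -1.32 ± 0.15, and AIF1 at -0.78 ± 0.10, -0.86 ± 0.10 and -1.38 ± 0.10. K5R passed the threshold for 2152 genes (1135 higher), K8R for 2074 (1074 higher) and K12R for 2793 (1441 higher). Of the genes called for K5R and K12R, 1038 were higher in both and 903 lower in both, where independent lists would share 295 and 248, and 0 went opposite ways. For K5R and K8R the shared numbers were 810 and 727 (220 and 184 for independent lists) with 3 opposite, and for K8R and K12R 930 and 820 (279 and 244) with 2 opposite. Part of these overlaps may come from the shared parental channel, though the intercept takes up what all arrays share. A change that appears only with several substitutions would also enter all 3 effects. With scaled arrays the counts for K5R and K8R were 1049 and 1360, and within the MDY470 arrays K5R, K8R and K12R gave 351, 758 and 1192.

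Across 5330 genes the K5R and K12R effects correlated with r = 0.943 (0.044 in simulated data without effects), K8R and K12R with 0.9 (0.074) and K5R and K8R with 0.888 (0.041). The K16R effect correlated less with them, with r = 0.581 for K5R (0.11), 0.54 for K8R (0.069) and 0.564 for K12R (0.037). The covariances exceeded the simulated ones by 0.0258 for K5R and K8R, 0.0355 for K5R and K12R, 0.0332 for K8R and K12R, 0.0222 for K5R and K16R, 0.0204 for K8R and K16R and 0.0278 for K12R and K16R. Without an intercept r was 0.855 for K5R and K12R, 0.775 for K8R and K12R, 0.737 for K5R and K8R, and 0.36, 0.279 and 0.31 for K16R with K5R, K8R and K12R, while data without effects gave between -0.29 and -0.21. The number of strains is small and genes are not independent, so no p-value is attached to these.

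**Figure D4:**
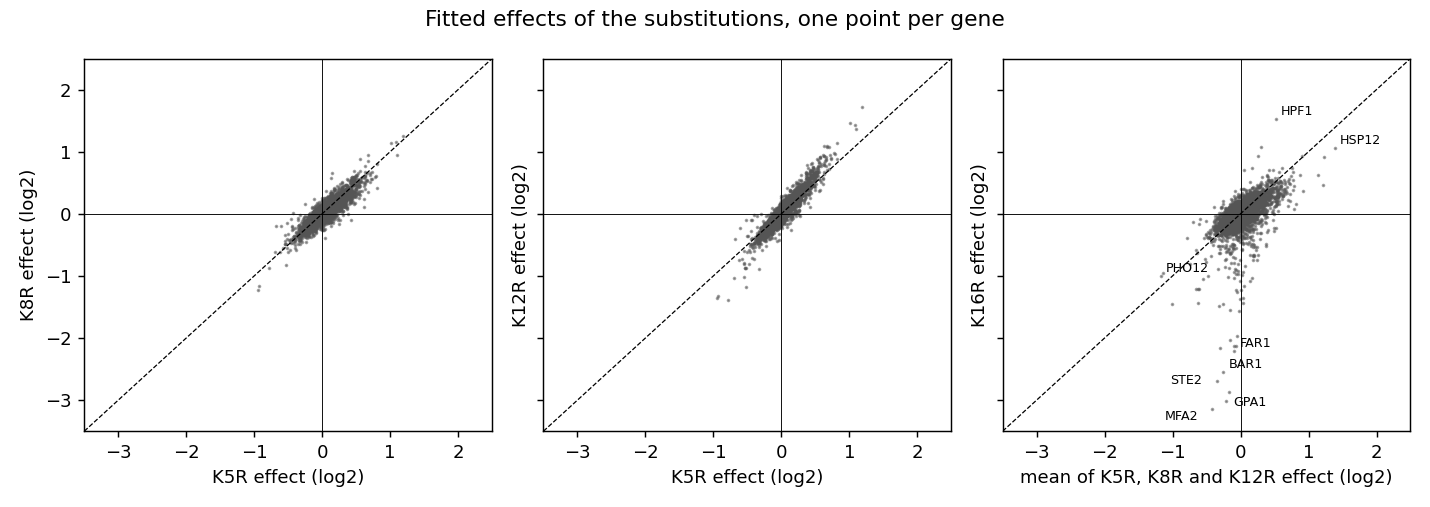
Site effects on the log2 scale, with a point per gene: K8R against K5R, K12R against K5R, and K16R against the mean of K5R, K8R and K12R. The mating genes GPA1, MFA2, STE2, BAR1 and FAR1 lie far below the diagonal in the last panel (GPA1 -3.01), and HPF1 lies above it.

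Only a handful of genes separated K5R, K8R and K12R from one another. In limma 11 genes passed, against 422 at an unadjusted p under 0.05. BNA5, kynureninase of NAD synthesis, had effects of -0.55 with K5R, -0.34 with K8R and -1.02 with K12R (adjusted p = 0.00259). YGP1, a secreted glycoprotein of starvation, had 0.38, 0.30 and 0.79 (adjusted p = 0.0308). The hexose transporter gene HXT6 had 0.53, 0.46 and 0.89, the glutamate decarboxylase gene GAD1 0.54, 0.45 and 0.87, the exoglucanase gene EXG1 0.36, 0.07 and 0.45, and AIF1 the values given above (adjusted p = 0.0396 for each of these 4 genes). This count is fragile: it ranged from 1 to 25 when single samples were left out. The samples behind these extremes were K5R/K8R replicate 3 (1 gene without it) and K8R replicate 3 (25 genes without it). The count was 0 with strain means and 160 without the quadruple mutant. Random regrouping of the strains broke every site effect at once and could not test this count alone, so chance stays open.

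K16R differed from the mean of the other 3 sites in 1079 genes, higher in 448 and lower in 631. GPA1 (difference -2.81) and STE2 (-2.35) were among the 26 lower by at least 2-fold, and HPF1 (1.01) was the 1 higher by at least 2-fold. All 7 a-specific genes and 22 of 29 haploid-specific and pheromone response genes had a lower effect of K16R, 7 and 23 adjusted over the list alone. Of 233 subtelomeric genes 87 had a lower and 8 a higher effect of K16R (100 and 12 adjusted over the list alone). Of 55 stress genes 26 had a lower effect of K16R and 2 a higher one (33 and 3 adjusted over the list alone), DDR2 with a difference of -0.74. Of the 2175 genes called for K16R 618 also differed from the mean of the other sites, and 17 of the 1079 were called for neither effect. K16R and the mean of the others shared 881 higher and 719 lower genes (363 and 332 for independent lists), and 121 went opposite ways. K16R shared 671 higher and 505 lower genes with K5R (53 opposite), 677 and 523 with K8R (48 opposite), and 789 and 612 with K12R (86 opposite). Independent lists would share 230 and 193, 218 and 190, and 292 and 257. As deposited, without centring, 55.5% of the 1127 differences were higher, against 41.5% after centring. The count was 1640 with scaled arrays, 501 within the MDY453 arrays and 542 within the MDY470 arrays.

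Set against the parental strain, most genes passed in the K16R mutant among the single mutants in this fit. The K16R mutant had 1019 genes past the threshold (477 higher and 542 lower, 3 samples), with HPF1 (1.47 ± 0.13), COS12 (1.05 ± 0.17), CSS1 (1.04 ± 0.12), YAR068W (0.84 ± 0.13) and MRPL31 (0.74 ± 0.17) as the highest. The MRPL31 call was lost without K16R replicate 3 (adjusted p = 0.209), whose label pairs a strain of the MDY453 set with MDY470. GPA1 (-2.91 ± 0.10), MFA2 (-2.64 ± 0.15), SNZ2 (-2.55 ± 0.13), STE2 (-2.46 ± 0.11) and CSS3 (-2.35 ± 0.19) were the lowest. The K12R mutant had 159 genes (99 higher), led by YGP1 (0.81 ± 0.13) and by HXT15, a hexose transporter gene, at -1.19 ± 0.15. The K5R mutant had 35 (29 higher), with the drug exporter gene AQR1 at 0.48 ± 0.10 and HXT13 at -0.66 ± 0.16. The K8R mutant had 18 (11 higher), with ENT5 at 0.75 ± 0.18 and the glycerol transporter gene STL1 at -1.04 ± 0.25. These 4 counts depend on the scaling, on a block by parental strain and on single samples. With that block more genes passed in the K5R mutant than in the K16R mutant (values below), though it removes by construction what the mutants share. With scaled arrays they were close together, 2099 for K16R, 1940 for K12R, 2014 for K5R and 1734 for K8R. The K5R count was 1, 0 and 0 without replicates 1, 2 and 3, the K8R count 2, 32 and 5, the K12R count 22 and 10 without replicates 2 and 3, and the K16R count 531 and 598 without replicates 2 and 3. As deposited, 93.1% of the K5R calls were higher, against 82.9% after centring and 52.3% with scaled arrays. For K8R these shares were 76.7%, 61.1% and 49.9%, and for K16R 61.6% as deposited against 46.8%.

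The double mutants without K16R shared their highest gene. DDR2 was the highest in K5R/K8R (1.03 ± 0.14), K5R/K12R (1.45 ± 0.16) and K8R/K12R (1.51 ± 0.18), in which 1115, 1529 and 1178 genes passed. HXT15 was the lowest in K5R/K8R (-1.41 ± 0.13), and COS10 in K5R/K12R (-2.10 ± 0.28) and K8R/K12R (-1.97 ± 0.32). With K16R, HPF1 was the highest in all 3 double mutants: 1.54 ± 0.12 in K5R/K16R, 1.29 ± 0.12 in K8R/K16R and 1.46 ± 0.12 in K12R/K16R, with 1308, 1145 and 1444 genes past the threshold. CSS3 was the lowest in K5R/K16R (-3.04 ± 0.17) and K8R/K16R (-2.94 ± 0.17), and COS10 in K12R/K16R (-3.22 ± 0.26). Of these calls 43.3%, 44.1% and 48.7% were higher after centring, and 63.9%, 62.6% and 63.3% as deposited. The count fell to 648 without K5R/K8R replicate 1, to 735 and 939 without K5R/K12R replicates 1 and 2, to 658 without K8R/K12R replicate 2, to 703 without K8R/K16R replicate 1 and to 740 without K12R/K16R replicate 1. With a block by parental strain, which removes by construction what the mutants share, the counts of all double mutants were far smaller (values below). DDR2 and HXT15 in K5R/K8R and COS10 in K8R/K12R then turned sign.

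More genes passed in the triple mutants in this fit: 3322 in K5R/K8R/K12R, 2231 in K5R/K8R/K16R, 3147 in K5R/K12R/K16R and 2582 in K8R/K12R/K16R. HSP12 led K5R/K8R/K12R (3.07 ± 0.14) and K8R/K12R/K16R (2.65 ± 0.15), and HPF1 led K5R/K8R/K16R (1.88 ± 0.13) and K5R/K12R/K16R (2.90 ± 0.12). The lowest genes were COS10 (-2.90 ± 0.25 in K5R/K8R/K12R and -3.34 ± 0.28 in K5R/K8R/K16R), MFA2 (-4.11 ± 0.14 in K5R/K12R/K16R) and AIF1 (-3.14 ± 0.14 in K8R/K12R/K16R). In the quadruple mutant 4086 genes passed (2056 higher and 2030 lower), 346 higher and 177 lower by at least 2-fold. HSP12 (4.31 ± 0.13), DDR2 (3.81 ± 0.13), PUT1 (3.47 ± 0.16), RTC3 (3.15 ± 0.14) and the chaperone gene HSP26 (3.10 ± 0.11) were its highest genes. MFA2 (-4.51 ± 0.13), PHO11 (-4.11 ± 0.14), PHO12 (-4.09 ± 0.16) and STE2 (-3.61 ± 0.10) were its lowest. The K5R/K8R/K16R count fell to 1445 without replicate 1. With scaled arrays it was 2302, below the 2447 of the double mutant K5R/K16R, and with a block by parental strain 117 against 172.

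In many genes the fitted effects of the sites did not simply add up, though chance was not excluded for their number. PIR3, a cell wall protein, had mean log2 ratios between -0.10 and 0.17 in every single and double mutant, 0.79 ± 0.17 (SD, n = 5) in K5R/K8R/K12R and 2.46 ± 0.09 (n = 4) in the quadruple mutant (adjusted p = 5.25e-12 for the 6 pairwise products together). YPS1, a cell surface protease, reached 0.88 ± 0.10 (n = 5) in K5R/K8R/K12R and 2.09 ± 0.18 (n = 4) in the quadruple mutant, and SSE2, a co-chaperone, 0.49 ± 0.25 and 1.67 ± 0.23. All 6 products were positive for PIR3, YPS1, CRG1, NCW2, ICL2 and SSE2, whose adjusted p-values lay between 5.25e-12 and 1.71e-10. In 1147 genes the products passed together. They were all positive in 612 and all negative in 407. The count was 615 without the quadruple mutant, 422 with scaled arrays, 395 within the MDY453 arrays and 79 within the MDY470 arrays. Random regrouping of the strains broke every site effect at once and could not test the products alone, so chance stays open for this count.

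The K16R effect changed with the number of other substitutions in 292 genes, upward in 197. For COS12 the K16R effect changed by -0.89 ± 0.13 (SE) with each other substitution (adjusted p = 3.31e-05). Its log2 ratio, which also holds the effects of the other sites, was 1.06 ± 0.27 (SD, n = 3) in the K16R mutant and -1.57 ± 0.25 (n = 4) in the quadruple mutant. The hexose transporter genes HXT15 and HXT16 had positive terms (0.78 ± 0.13 and 0.76 ± 0.13), as did the protease gene YPS6 (0.66 ± 0.10), AFB1 (0.60 ± 0.10) and NEJ1 (0.46 ± 0.08). HXT15 was already low in the K16R mutant (-1.92 ± 0.06, SD, n = 3) and at -1.50 ± 0.42 (n = 4) in the quadruple mutant. The count was 38 without the quadruple mutant, 56 with strain means, 132 without quadruple mutant replicate 3, 164 without K5R/K8R/K12R replicate 1 and 507 without K16R replicate 2. It was 50 within the MDY453 arrays and 0 within the MDY470 arrays, which hold neither the quadruple mutant nor K5R/K12R/K16R, and 54.1% of the calls were upward as deposited and 78% with scaled arrays, against 67.5%.

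Profiles measured against different parental strains share no control RNA. Between 14 mutants measured against MDY453 and 13 against MDY470, the mean r across genes was 0.769 for the same mutant. For different mutants it was 0.673 where both had K16R, 0.583 where neither had it and 0.47 where 1 of them had it. Pairs alike in K16R exceeded unlike pairs by 0.162 (exact permutation p = 0.00016 over 6435 assignments, two-sided). With each gene centred on its mean over the mutants of a set the difference was 0.447 (exact permutation p = 0.00062). RRP5, a ribosome biogenesis factor, was the 1 gene past the threshold for a site effect that differed between the sets. Its K12R effect was -0.32 ± 0.06 against MDY453 and 0.18 ± 0.08 against MDY470 (limma adjusted p = 0.0496). For K5R, K8R and K16R limma found 0 such genes, against 440, 329 and 466 at an unadjusted p under 0.05. For K12R 934 of 5540 genes were under that unadjusted p, so further K12R effects may differ between the sets.

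Of the 11 histone genes, both H4 genes were lower with K16R, HHF1 by -0.33 ± 0.06 and HHF2 by -0.28 ± 0.05, and the H2A.Z gene HTZ1 rose (0.14 ± 0.05). The remaining 8 did not pass: HTB2 0.14 ± 0.06, HTA2 0.08 ± 0.06, HTB1 0.04 ± 0.06, HHT2 0.03 ± 0.05, HHT1 0.02 ± 0.05, HHO1 0.01 ± 0.05, HTA1 0.00 ± 0.05 and CSE4 -0.10 ± 0.06. Adjusted over the list alone the numbers were the same, 1 higher and 2 lower, and the list was not called (adjusted p = 0.807). With the mean of K5R, K8R and K12R 9 rose and 1 fell, also adjusted over the list alone: HTB2 0.30 ± 0.04, HTB1 0.28 ± 0.04, HTA2 0.21 ± 0.04, HTA1 0.17 ± 0.03, HHT2 0.12 ± 0.03, HTZ1 0.11 ± 0.03, HHT1 0.10 ± 0.03, CSE4 0.09 ± 0.04, HHO1 0.07 ± 0.03, HHF1 -0.09 ± 0.03 and, not past the threshold, HHF2 -0.05 ± 0.03 (list adjusted p = 0.062). HHT2 turned to -0.04 with scaled arrays and HHF1 to 0.07 without an intercept. In limma the HHF1 call for these sites was lost without quadruple mutant replicate 4 (adjusted p = 0.0945). The HHO1 call was lost without single samples, such as quadruple mutant replicate 1 (adjusted p = 0.0695). A substitution of single codons does not remove a probe's target, so the H4 probes do not check the labels.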

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

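The tests on mating genes, on additivity and on the parental sets for subtelomeric genes were chosen only after those results had been seen, as were the conditions on the SE for subtelomeric genes and for compression. The patterns themselves were also known before the other tests were written. Among 48 groups of 4 or 5 samples 6 had a sample far from the rest, and chance gives about 1 in 20. K5R/K8R replicate 2 had 236 values at the ratio limit, against 47 to 74 in the other samples of that mutant. In the same sample DDR2 stood at 1.51, against 0.815 to 0.92. K5R/K8R/K12R replicate 1 had 210 values at the limit (58 to 85 in the others). K5R/K8R/K12R replicate 5 had an SD over genes of 0.406, below the 0.449 to 0.465 of the others. In quadruple mutant replicate 4 DDR2 stood at 3.16 (4.05 to 4.07 in the others) and PHO12 at -2.95 (-4.57 to -4.46). Leaving out the 3 arrays with the most limit values moved the count of genes whose K16R effect changes with number from 292 to 148 and the count separating K5R, K8R and K12R from 11 to 18. The K12R effect on RRP5 differed between the sets by a test of the interaction, -0.318 against MDY453 and 0.176 against MDY470 (limma adjusted p = 0.0496).

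Loss of a-specific and haploid-specific expression with K16R was set against technical explanations and a switch to haploid alpha cells. If the cultures with K16R held haploid alpha cells, haploid genes used by both mating types would stay level. Their median K16R effect was -1.56 over 7 genes and the highest alpha-specific effect was 0.22, which argues against haploid alpha cells. Cells that hold both mating types, such as diploids after a switch, were not covered by this test. A difference between the parental sets is argued against by the a-specific median of -2.60 over 7 genes within the MDY453 arrays and -2.15 over 6 genes within the MDY470 arrays. Expression of the silent mating cassettes, which would give a haploid cell both mating-type regulators and is a candidate explanation in textbook terms, stays open. No rise was seen: 0 of 4 alpha cassette and MAT probes passed, and the largest K16R effect among the 6 cassette and MAT probes was 0.16. Without intensities it is not known whether these probes detect their RNA, so a small rise could be missed.

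Lower expression near chromosome ends with K16R stayed open for each explanation. Families were set by a name prefix shared by at least 3 subtelomeric genes, and outside them 37.3% of 158 genes were lower, against 17.7% beyond 40 kb. Duplicated genes such as SNZ2 and SNZ3 remained among the 158: 30 had a prefix shared with another subtelomeric gene (12 lower) and 69 only a systematic name (24 lower). Without both kinds 23 of 59 (39%) were lower, and in families 20 of 75. With the whole list's estimated correlation (0.146) the SE of the 39% was 19.5, so shared probes stay open. Negative K16R effects were 10.3 percentage points more frequent within 20 kb than beyond 40 kb in the MDY453 arrays and 16.3 in the MDY470 arrays, but with that correlation the SE was 19 and 18.5, so a cause in 1 set is not excluded. A hypothesis that silent chromatin may reach further in was not settled by 36% lower among 175 genes between 5 and 20 kb (SE 18.6 with that correlation), and camera lost the call with an estimated correlation (adjusted p = 0.559).

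Departure from additivity was set against compression of large ratios by the arrays, which would make the products oppose the change. The mean product had the sign of the sum of the 4 single mutants in 58.1% of the 1147 genes (SE 2.22 over left-out strains). That lies over 2 SE above 50%, which argues against compression as the whole cause, but below the bound of 60% first set for this test, so compression in part of the genes stays open. The quadruple mutant alone did not account for every gene, as 615 passed without it, 356 of them shared with the 1147. For the others of the 1147 it may be the source, and the 615 were not set against regrouped strains. Other regroupings of the strains bear on this count: 5 of 100 gave as many genes, with 2236 as the highest other, so chance could not be excluded. No biological explanation was tested.

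The 30 strains were also regrouped for the other counts, with 100 splits drawn and the real split included. For a single site only that site was regrouped, and this excluded chance for the counts of the single sites. For K16R 1 of 100 splits gave as many genes (2175 real, 381 as the highest other), for K5R 1 (2152, 827), for K8R 1 (2074, 298), for K12R 1 (2793, 1158) and for the mean of these 3 sites 1 (3538, 1401). For the difference of K16R from that mean 2 splits gave as many (1079, with 1482 as the highest other), and for the change of the K16R effect with number 4 (292, with 980 as the highest other). For the mean and for these 2 results the splits moved whole strains and broke every site effect at once. They cannot test the difference or the change with number alone, so no conclusion is drawn for these 2 counts. For the differences among K5R, K8R and K12R 7 splits gave as many (11, 1137), so chance was not excluded. For the change with number and for the differences among K5R, K8R and K12R the highest count was several times the real one. This points to a structure of the samples whose nature was not tested.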

How the results depend on the processing

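Spot intensities were not used here, so signal over background is unknown and a probe near background cannot show a fall. Block numbers do not pair samples: differences between the parental sets correlated over 66 pairs of 12 mutants with median r 0.0798 (-0.248 to 0.503, 31 over 0.1), and differences between replicate numbers over 45 pairs of 10 mutants with median r 0.0375 (lowest -0.303, 18 over 0.1). For mutants against 0 the block by parental strain removes by construction what the mutants share. Turning the sign of the (s) arrays is not supported by the arrays, as no pair of arrays correlated below 0. Of 388 calls of named genes 14 were lost on leaving out at least 1 sample and 0 changed sign. Leaving out a whole strain gave 94 to 658 genes for K16R by number and 1 to 29 for differences among K5R, K8R and K12R. The cause was not tested for any value below.

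Counts that moved, by setting, follow; names of sites stand for genes past the threshold. With values as deposited, not centred: differences among K5R, K8R and K12R 4. Mutants: K5R 72, K8R 30. With arrays scaled to 1 median absolute deviation: K5R effect 1049, K8R effect 1360, K16R minus that mean 1640, differences among K5R, K8R and K12R 120, K16R by number 173, pairwise products 422. Mutants: K12R 1940, K16R 2099, K5R 2014, K5R/K16R 2447, K5R/K8R 2223. Further mutants: quadruple mutant 2697, K8R 1734, K8R/K12R 2090, K8R/K16R 2098. Sign reversed: COS10 with the mean of K5R, K8R and K12R (0.0267), STE2 with the mean of K5R, K8R and K12R (0.254), MFA2 with the mean of K5R, K8R and K12R (0.264), BAR1 with the mean of K5R, K8R and K12R (0.252), STE6 with the mean of K5R, K8R and K12R (0.318), NEJ1 with the mean of K5R, K8R and K12R (0.144), COS6 with the mean of K5R, K8R and K12R (-0.037), HHT2 with the mean of K5R, K8R and K12R (-0.0424). With no strain block: K16R minus that mean 1706, differences among K5R, K8R and K12R 75, K16R by number 598, pairwise products 1885. Mutants: K12R 429, K5R 241, K8R 85, K8R/K12R 1894. With 1 mean per strain: differences among K5R, K8R and K12R 0, K16R by number 56. Mutants: K12R 73, K5R 13, K5R/K16R 816, K5R/K8R 618, K8R/K12R 382. Further mutants: K8R/K16R 688. With a block by biological replicate number: differences among K5R, K8R and K12R 7. Mutants: K5R 77, K8R 40. With a block by parental strain, mutants: K12R/K16R 142, K16R 385, K5R 473, K5R/K12R 39, K5R/K12R/K16R 730. Further mutants: K5R/K16R 172, K5R/K8R 86, K5R/K8R/K12R 1596, K5R/K8R/K16R 117, K8R 374. Further mutants: K8R/K12R 11, K8R/K12R/K16R 463, K8R/K16R 150. Sign reversed: HXT15 in H4 K12R versus parental (0.56), HXT13 in H4 K5R versus parental (0.893), DDR2 in H4 K5R/K8R versus parental (-0.268), HXT15 in H4 K5R/K8R versus parental (0.364), COS10 in H4 K8R/K12R versus parental (0.0457).

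With the 13 arrays labelled (s) left out: differences among K5R, K8R and K12R 2, K16R by number 104. Mutants: K12R 14, K16R 423, K5R 0, K5R/K12R 437, K5R/K16R 796. Further mutants: K5R/K8R 385, K8R 4, K8R/K12R 731, K8R/K16R 516. With the arrays labelled (s) averaged with the other array of the strain: differences among K5R, K8R and K12R 0. Mutants: K12R 29, K16R 560, K5R 0, K5R/K16R 847, K5R/K8R 715. Further mutants: K8R 11. With the sign of the arrays labelled (s) turned: K16R effect 3, K5R effect 0, K8R effect 35, K12R effect 978, K16R minus that mean 0, differences among K5R, K8R and K12R 0, K16R by number 0, pairwise products 419. Mutants: K12R 0, K12R/K16R 0, K16R 0, K5R 0, K5R/K12R 0. Further mutants: K5R/K12R/K16R 1, K5R/K16R 0, K5R/K8R 0, K5R/K8R/K12R 1009, K5R/K8R/K16R 2. Further mutants: K8R 1, K8R/K12R 69, K8R/K12R/K16R 0, K8R/K16R 0. Sign reversed: NEJ1 K16R by number interaction (-0.0297), MRPL31 in H4 K16R versus parental (-0.397), ENT5 in H4 K8R versus parental (-0.68), STL1 in H4 K8R versus parental (0.894). With array weights: K16R minus that mean 2101, differences among K5R, K8R and K12R 79, K16R by number 64. Mutants: K12R 1736, K12R/K16R 2861, K16R 2349, K5R 2203, K5R/K12R 2345. Further mutants: K5R/K16R 3233, K5R/K8R 2207, K8R 1418, K8R/K12R 2740. With only the MDY453 arrays: K16R effect 1338, K5R effect 1397, K16R minus that mean 501, differences among K5R, K8R and K12R 0, K16R by number 50, pairwise products 395. Mutants: K12R 0, K12R/K16R 257, K16R 71, K5R 0, K5R/K12R 97. Further mutants: K5R/K16R 194, K5R/K8R 19, K5R/K8R/K12R 2036, K5R/K8R/K16R 845, K8R 0. Further mutants: K8R/K12R/K16R 1236, K8R/K16R 195. With only the MDY470 arrays: K16R effect 685, K5R effect 351, K8R effect 758, K12R effect 1192, mean effect of K5R, K8R and K12R 1699, K16R minus that mean 542, differences among K5R, K8R and K12R 0, K16R by number 0, pairwise products 79. Mutants: K12R 61, K12R/K16R 2463, K5R 0, K8R 32, K8R/K12R 2985. Sign reversed: PST1 with K16R (-0.0622), STE2 with the mean of K5R, K8R and K12R (0.12), MFA2 with the mean of K5R, K8R and K12R (0.2), STE6 with the mean of K5R, K8R and K12R (0.173), COS6 with the mean of K5R, K8R and K12R (-0.00937). Without an intercept: K16R effect 1259, K5R effect 977, K8R effect 738, K12R effect 1776, differences among K5R, K8R and K12R 0, K16R by number 2240. Correlations of site effects: K5R and K8R 0.737, K5R and K16R 0.36, K8R and K12R 0.775, K8R and K16R 0.279, K12R and K16R 0.31. Sign reversed: SAG1 with K16R (-0.027), PAU24 with K16R (-0.0793), ADH1 with K16R (0.032), TPI1 with the mean of K5R, K8R and K12R (0.0106), HHF1 with the mean of K5R, K8R and K12R (0.0703).

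List calls changed most with the correlation estimated per list, which left 2 lists for K16R and 1 for the mean of K5R, K8R and K12R. With fry 19 and 31 lists were called. Of the 11 K16R calls 10 were kept with fry, 10 with no strain block, 11 within the MDY453 arrays and 8 within the MDY470 arrays. Of the 15 calls for the mean of the other sites 15, 15, 15 and 11 were kept. Within the MDY470 arrays the cytosolic ribosomal protein list turned from lower to higher with K16R (adjusted p = 0.0431).

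These settings were chosen after the data had been seen. With every probe, unnamed included: differences among K5R, K8R and K12R 2. Without the quadruple mutant: K16R minus that mean 1724, differences among K5R, K8R and K12R 160, K16R by number 38, pairwise products 615. Mutants: K12R 468, K5R 290, K8R 119, K8R/K12R 1806. Without the 3 arrays with the most limit values: differences among K5R, K8R and K12R 18, K16R by number 148. Without the K16R array with mixed labels, mutants: K16R 593. That array is K16R replicate 3, whose removal gave 598 with the strain correlation kept from all samples and 593 with it estimated again.

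Leaving out 1 sample at a time gave 10 to 114 for the K12R mutant, 740 to 1515 for the K12R/K16R mutant, 531 to 762 for the K16R mutant, 0 to 1 for the K5R mutant. It gave 735 to 1335 for the K5R/K12R mutant, 648 to 1019 for the K5R/K8R mutant, 1445 to 1797 for the K5R/K8R/K16R mutant, 2 to 32 for the K8R mutant. It also gave 658 to 1130 for the K8R/K12R mutant, 703 to 1121 for the K8R/K16R mutant, 1 to 25 for differences among K5R, K8R and K12R, 132 to 507 for K16R by number..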

Other observations

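The comparison of stress with ribosome biogenesis genes under K16R alone was chosen only after the result had been seen. Other gene lists showed single members with clear changes while no list as a whole was called. Of 32 iron regulon genes 7 rose and 4 fell with K16R, with the siderophore transporter gene ENB1 at -0.77 ± 0.13 (SE, 54 samples), FRE3 at -0.56 ± 0.10, FRE4 at -0.33 ± 0.06 and CTH1 at 0.29 ± 0.04 (limma; list adjusted p = 0.784). With the mean of K5R, K8R and K12R 12 rose and 6 fell, HMX1 at 0.33 ± 0.04, FRE4 at -0.35 ± 0.04, ISU2 at -0.19 ± 0.02 and CTH1 at 0.19 ± 0.03 (adjusted p = 0.5). Of 12 zinc genes 4 rose and 1 fell with K16R, ZRT1 at 0.28 ± 0.05 and ZPS1 at -0.20 ± 0.06 (adjusted p = 0.216), and 4 rose and 4 fell with the other sites, FET4 at -0.38 ± 0.07 and IZH2 at -0.25 ± 0.04 (adjusted p = 0.807). Of 23 thiamine genes 12 rose and 4 fell with the other sites, SNZ1 at 0.64 ± 0.06 and THI12 at 0.53 ± 0.05 (adjusted p = 0.0747). Of 8 NAD biosynthesis genes 2 rose and 1 fell with K16R, BNA5 at -0.63 ± 0.08 and BNA2 at 0.40 ± 0.07 (adjusted p = 0.961), and 4 rose and 2 fell with the other sites, BNA2 at 0.65 ± 0.04 and BNA1 at 0.36 ± 0.03 (adjusted p = 0.5). Adjusted over the list alone, the numbers higher and lower were the same for iron and for thiamine. For zinc they were 4 and 2 with K16R and 4 and 5 with the other sites, and for NAD 2 and 2 with K16R and 4 and 2 with the other sites.

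Sugar and lipid genes were divided too. Of 20 hexose transporters 5 rose and 6 fell with K16R (6 and 6 adjusted over the list alone), HXT5 at 0.41 ± 0.07, HXT15 at -0.71 ± 0.13, HXT16 at -0.69 ± 0.13 and HXT13 at -0.60 ± 0.12 (limma; list adjusted p = 0.991). With the mean of K5R, K8R and K12R 10 rose and 2 fell, also adjusted over the list alone, HXT6 at 0.63 ± 0.04, HXT7 at 0.57 ± 0.04 and HXT4 at 0.32 ± 0.04 (adjusted p = 0.0922). Of 20 galactose and maltose genes 4 rose and 5 fell with K16R, also adjusted over the list alone, MPH2 at -0.56 ± 0.10, MPH3 at -0.33 ± 0.05 and GCY1 at 0.39 ± 0.06 (adjusted p = 0.706), and 9 rose and 7 fell with the other sites, also adjusted over the list alone, GCY1 at 0.48 ± 0.04 and GAL3 at 0.28 ± 0.04 (adjusted p = 0.5). Of 20 glycolysis and fermentation genes 2 rose and 3 fell with K16R, also adjusted over the list alone, PDC6 at 0.32 ± 0.05 and TPI1 at -0.24 ± 0.04 (adjusted p = 0.913), and 5 rose and 4 fell with the other sites (3 and 4 adjusted over the list alone), PDC6 at 0.40 ± 0.03 (adjusted p = 0.991). ADH1 was at -0.15 ± 0.05 with K16R and 0.03 without an intercept, and TPI1 at -0.18 ± 0.03 with the other sites and 0.01 without an intercept. Of 24 ergosterol genes 6 fell with K16R, also adjusted over the list alone, IDI1 at -0.26 ± 0.07 and ERG12 at -0.22 ± 0.04 (adjusted p = 0.286), and 4 rose and 9 fell with the other sites, also adjusted over the list alone, ERG12 at -0.33 ± 0.03 (adjusted p = 0.148). Of 18 phospholipid genes 7 rose and 2 fell with K16R, also adjusted over the list alone, OPI3 at 0.53 ± 0.09 and FAS1 at 0.32 ± 0.06 (adjusted p = 0.14), and 8 rose and 5 fell with the other sites, also adjusted over the list alone, OPI3 at 0.69 ± 0.06 and CHO1 at 0.17 ± 0.02 (adjusted p = 0.294).

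The lists of G1/S, DNA damage, silencing factor, mannoprotein and COS genes were not called either. Of 42 G1/S genes 5 rose and 9 fell with K16R (4 and 9 adjusted over the list alone), the cyclin gene CLN2 at -0.32 ± 0.06 and GIC2 at -0.31 ± 0.04 (limma; list adjusted p = 0.528), while with the other sites 15 rose and 5 fell, also adjusted over the list alone, GIC2 at 0.30 ± 0.02 (adjusted p = 0.458). Of 19 DNA damage genes 7 rose and 3 fell with K16R (10 and 4 adjusted over the list alone), the photolyase gene PHR1 at -0.47 ± 0.05 and RFX1 at 0.29 ± 0.05 (adjusted p = 0.345), and 11 rose and 4 fell with the other sites (12 and 4 adjusted over the list alone), RNR4 at 0.45 ± 0.04 and RNR2 at 0.43 ± 0.04 (adjusted p = 0.0922). PEX2 entered this list only through an alias shared with RFX1. Of 26 chromatin silencing factors 4 rose and 6 fell with K16R, also adjusted over the list alone, SAS5, a subunit of the acetyltransferase that acts on H4 lysine 16, at -0.32 ± 0.04, HDA1 at -0.27 ± 0.07 and BDF2 at 0.29 ± 0.05 (adjusted p = 0.553), and 7 rose and 9 fell with the other sites, also adjusted over the list alone, ORC1 at -0.30 ± 0.03 and BDF1 at 0.23 ± 0.03 (adjusted p = 0.662). Of 8 anaerobic cell wall mannoprotein genes 4 rose with K16R, also adjusted over the list alone, TIR4 at 0.40 ± 0.08 (adjusted p = 0.458), and 4 rose and 1 fell with the other sites, also adjusted over the list alone, TIR4 at 0.45 ± 0.05 and TIR3 at -0.32 ± 0.04 (adjusted p = 0.456). Of the COS genes 8 rose and 3 fell with the other sites, also adjusted over the list alone (adjusted p = 0.595), COS111 at 0.19 ± 0.03. COS6 was at 0.14 ± 0.04 and turned to -0.04 with scaled arrays and -0.01 within the MDY470 arrays. Of 958 testable probes without a gene name 284 passed with K16R (197 higher and 87 lower) and 381 with the mean of K5R, K8R and K12R (230 and 151).

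Stress and ribosome biogenesis genes moved apart as substitutions were added. The median log2 ratio of the stress list was 0.148 in strains with 1 substitution, 0.305 with 2, 0.944 with 3 and 1.51 with 4, while the ribosome biogenesis median was -0.0351, -0.0541, -0.177 and -0.374. A hypothesis is that 1 shared shift, such as slower growth, may lie behind both. After the mean of each number of substitutions was removed, the list medians correlated over the 30 strains with r = -0.738 (permutation p = 7e-05) and rho = -0.751 (permutation p = 2e-05). Without the 2 strains farthest from the median r was -0.707, within the MDY453 arrays -0.761 (16 strains) and within the MDY470 arrays -0.741 (13 strains). Other values, looked at only after that result had been seen, go against 1 shift as the whole cause. With K16R 43 of 55 stress genes rose while 13 of 117 biogenesis genes fell and 11 rose (list adjusted p = 0.638), and within the MDY470 arrays both lists were higher with K16R (adjusted p = 2.43e-06 for stress and 0.000322 for biogenesis at the preset correlation). Over all arrays an estimated correlation gave adjusted p = 0.18 and 0.948 for K16R, so this evidence is weak too. Growth was not measured here, so the hypothesis stays open.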
